A study of Campylobacter jejuni with 9 samples.

How the data were processed

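RNA of Campylobacter jejuni PT14 was measured by RNA sequencing in 9 libraries, 3 each from spiral cells in exponential phase, spiral cells in stationary phase and filamentous cells in stationary phase. Per the labels, 3 independent biological replicates were grown in 500 ml of minimum essential medium with 10 mM sodium pyruvate at 37 °C, in about 7% oxygen and with shaking at 100 rpm, for 30 h. The same growth text stands with all 9 libraries, so the hour at which exponential cells were harvested is not given in the sources used here. Short spiral cells were parted from filaments on a nitrocellulose membrane with 0.8 µm pores, total RNA was extracted with Trizol and purified on RNeasy columns, ribosomal RNA was depleted with Ribo-Zero, and libraries were made with the NEBNext Ultra directional kit, per the labels.

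Base calls and demultiplexing used CASAVA 1.8.2 and bcl2fastq 1.8.4, per the submitters' processing notes. The aligner, the counting program, the genome build, the strand setting of the counting and the handling of reads with several matches are not given in the sources used here. Each library has its own table of 1657 features with their PT14 coordinates, and no replicates were pooled. The deposited counts are whole numbers of reads per gene, given both as unique gene reads and as total gene reads, per the file headers. The difference between these 2 columns is called reads with several matches here. The authors also gave TPM, which summed to the same total in each library, and RPKM, per the file headers. In the deposited RPKM the denominator was a single number per library between 4316770 and 10430700 reads, of which the gene reads made up 15.5% to 29.0%. What the other reads in that denominator were is not given in the sources used here. TPM and RPKM were used only for such checks of the files, and every result below rests on the total gene reads.

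In the files, 247 features carry a gene symbol and 1410 carry only a locus tag, with no product names. The files do not pair tags with names. Of the 247 symbols, 246 were found in a RefSeq gene table of another C. jejuni strain (assembly ASM908v1), which was used for no coordinates. Coordinates are those in the files, counted from 1 on the PT14 chromosome, and the feature lengths are coding lengths. The 9 features with ribosomal RNA tags were left out of library sizes and tests because ribosomal RNA was depleted on purpose. The 41 features with transfer RNA tags drew between 10 and 49 reads per library. Neighbouring features overlapped in 602 places, and the counts of overlapping genes are uncertain.

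Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low counts were removed with filterByExpr, which left 1554 genes, libraries were scaled by TMM, and one quasi-likelihood model with a term per group and robust estimation was fitted to all 9 libraries, with 6 residual degrees of freedom. The biological coefficient of variation was 18.1%. The contrasts tested were filament minus spiral cells in stationary phase, stationary minus exponential phase in spiral cells, and stationary filaments minus exponential spiral cells. A gene was called changed at an adjusted p below 0.05, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 1554 genes. Values after ± are standard errors for log2 fold changes and SDs for normalised read counts, with n = 3 libraries per group throughout. Normalised read counts are CPM values scaled by TMM.

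Gene lists for 35 functions were written before the data were examined, as were the contrasts, the tests, the rule for named genes and most alternative settings. A list was tested if 4 or more of its members were tested, which held for 16 lists. These covered flagellar filament, hook and rod; flagellar export, motor and regulators; peptidoglycan and cell shape; DNA replication; DNA repair; ribosomal proteins; aminoacyl-tRNA synthetases; translation factors; RNA polymerase and transcription factors; citric acid cycle and pyruvate metabolism; gluconeogenesis; amino acid biosynthesis; purine and pyrimidine biosynthesis; heat shock, chaperones and proteases; fatty acid and phospholipid synthesis; and Sec, Tat and outer membrane assembly. Lists that had been defined by product name, such as ribosomal proteins and aminoacyl-tRNA synthetases, were translated to symbols because the files hold no products. All other lists had fewer than 4 members in the files, among them those for chemotaxis, cell division, oxidative stress, iron uptake and capsule, because most genes carry only a tag. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and p was adjusted over the 16 lists of a comparison. Where no count adjusted over the list alone is given, it equalled the count over all genes. Camera compares a list with the other genes. The fry test, an alternative, asks whether the genes of a list move on balance one way and does not compare them with other genes.

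Named genes were chosen by rule for each comparison. They are the 6 largest rises and the 6 largest falls among changed genes at or above the median level, with a symbol, whose 3 libraries in one group all lay above the 3 of the other. Added to these are up to 3 members with the smallest p of each list that passed and a fixed set of genes, of which rpsA, dnaA, recA, fliA and dnaK are named in the files. Members of lists are named as examples outside this rule.

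Counting precision was set by 1187098 to 2202132 gene reads per library. The procedure was tested on simulated data with the means and library sizes of the 1554 genes. For filaments against spiral cells it recovered 88.1% of 2-fold and 29.9% of 1.5-fold changes, for stationary against exponential spiral cells 83.6% and 22.4%, and for filaments against exponential cells 91.0% and 40.3%. False calls were 4.70%, 2.16% and 4.35% of calls in the same order. Most 1.5-fold changes were thus missed in the simulated data. Only 66 or 67 genes were changed at each fold there, against 688 to 922 genes called in the real comparisons. Recovery in the real data may therefore differ, since the adjusted p depends on how many genes change.

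Alternatives changed one choice at a time, except that the DESeq2 Wald test changed both the test and the scaling. They were DESeq2 1.42.0 size factors, library totals with no TMM, the DESeq2 Wald test, limma-voom, no filter and a stricter filter on low counts, ribosomal RNA features kept, a fit of only the 6 libraries compared, another dispersion estimate, the replicate number as a block, leaving out each library, and for lists an estimated correlation and fry. Added after the data had been seen were unique reads, leaving out the 2 libraries that stood apart, leaving out genes with a converging neighbour, and a background of genes with symbols. A converging neighbour is the adjacent gene on the other strand whose end faces the end of the gene, within 200 bases. Intervals for medians and correlations are 95% bootstrap intervals from 2000 draws over genes, which are not independent replicates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.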

Results

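RNA from 9 libraries of the enteric bacterium Campylobacter jejuni, strain PT14, was compared between spiral cells, the short helical form, and filaments, which are elongated cells. The groups were spiral cells in exponential phase, spiral cells in stationary phase and filaments in stationary phase, with 3 biological replicates each. Reads assigned to genes numbered 1399071, 1718669 and 1252814 in exponential spiral cells, 1459956, 1394454 and 1569771 in stationary spiral cells, and 1657136, 1187098 and 2202132 in filaments. The chaperonin gene groEL alone took 0.828% to 1.05% of gene reads in exponential spiral cells, 5.98% to 10.3% in stationary spiral cells and 3.51% to 3.79% in filaments. The 10 most abundant genes took 18.95% to 21.5%, 29.0% to 38.1% and 21.9% to 25.1% in the same order.

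The 3 groups lay apart in a principal component analysis of log2 CPM. The first component held 59.0% of the variance and parted exponential from stationary libraries. The second held 25.6% and parted stationary spiral cells, at 13.8 to 15.3, from filaments, at −18.2, −17.4 and −9.25. The last of these values, nearer to the spiral cells, belonged to filament replicate 3. Exponential replicate 1 stood apart on the third component (7.04% of the variance), at 14.7 against −8.99 and −8.45. Filament replicates 1 and 2 differed by a chi-squared of 2.22 per degree of freedom over genes, against 6.56 to 67.4 in the other pairs within a group. Whether these 2 are independent cultures, as the labels state, cannot be settled from the counts, and the standard errors of both filament comparisons assume that they are. Ribosomal RNA features held 0.360% to 0.961% of gene reads in exponential libraries, 1.15% to 2.97% in stationary spiral cells and 1.07% to 6.90% in filaments.

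**Figure D1:**
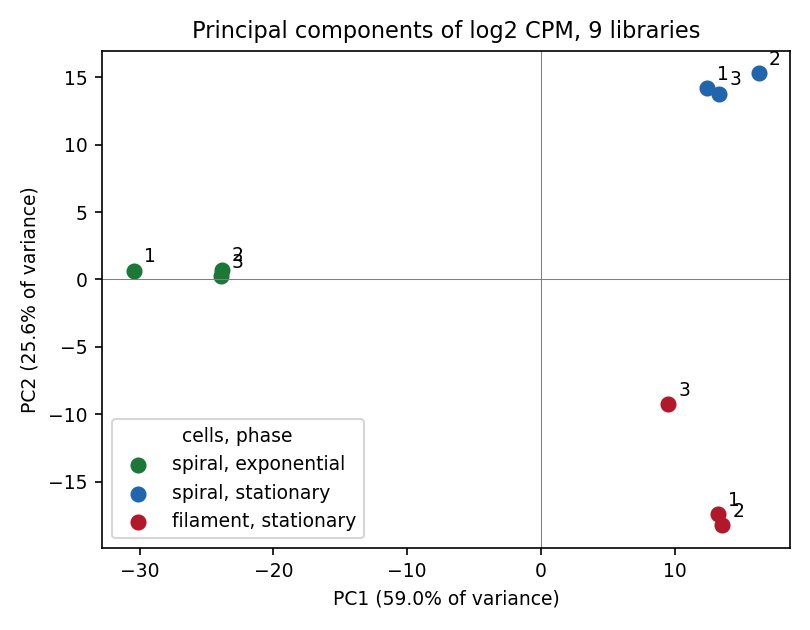
Principal components of log2 CPM in the 9 libraries, with component 1 (59.0% of variance) on the x axis, component 2 (25.6%) on the y axis, colours for the groups and numbers for the replicates. Filament replicate 3 lay at −9.25 on component 2, between the other filaments (−17.4 and −18.2) and the stationary spiral cells (13.8 to 15.3).

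Genes that face a neighbour on the other strand end to end had higher levels than other genes in every group. In exponential cells the median was 447 CPM per kilobase in the 318 tested genes with a converging neighbour within 200 bases and 159 in the other 1236 genes. The ratio was 2.82 there, 2.69 in stationary spiral cells and 2.59 in filaments. Among genes in tight series on the same strand (gaps under 30 bases), those that ended at a converging gene lay above the gene upstream of them, with library medians between 1.32 and 1.92 (log2, 170 pairs). Genes inside a series lay below the gene upstream, with medians between −0.48 and −0.25 (528 pairs). The libraries were made with a directional kit, and the strand setting of the counting is not given in the sources used here. The values of genes with an overlapping or converging neighbour are therefore uncertain, and no gene was shown to be free of reads from the opposite strand. Genes chosen by the rule for a comparison are listed there if they have a converging neighbour. The same limit holds for groEL and fliP where they are named in other comparisons.

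**Figure D2:**
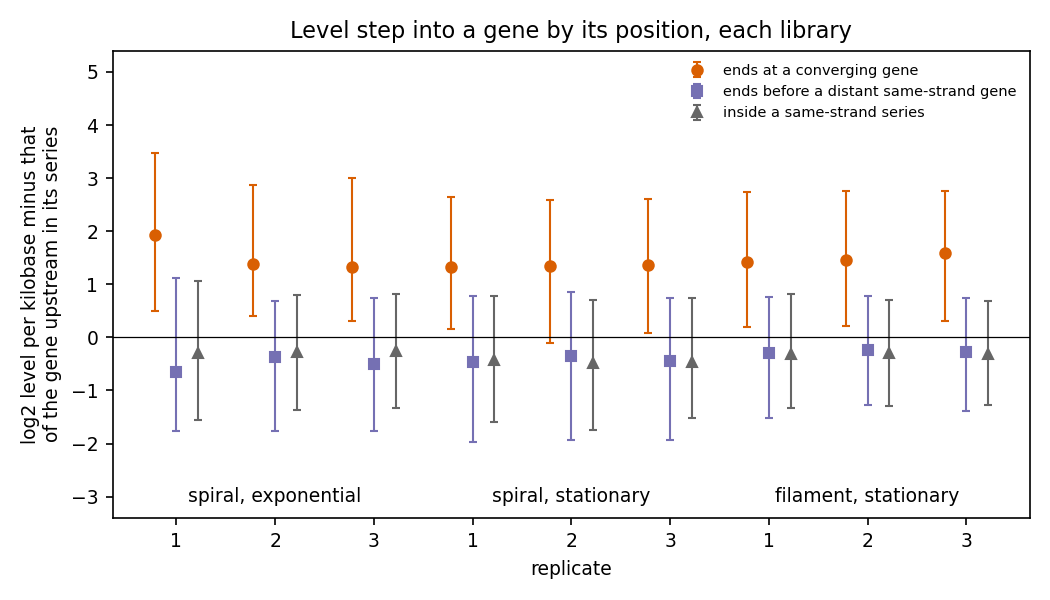
Level of a gene minus that of the gene upstream in its same-strand series (log2 of reads per kilobase, y axis) in each of the 9 libraries (x axis), where points are medians over gene pairs and bars span quartiles. Genes that end at a converging gene had medians of 1.32 to 1.92, against −0.65 to −0.24 for genes that end before a distant gene on the same strand.

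The comparison of filaments with spiral cells, both in stationary phase, asks which transcripts differ between the morphotypes. The morphotypes were parted on a membrane, so differences of cell form cannot be told apart here from effects of that parting. Lower in filaments were several flagellar hook, rod and ring genes, among them flgI, which encodes the P ring protein (−2.27 ± 0.37 log2, n = 3 and 3), flgH, which encodes the L ring protein (−1.97 ± 0.33), flgD for the hook cap (−1.97 ± 0.34) and flgB for a rod protein (−1.95 ± 0.37). The chaperonin genes groES (−2.25 ± 0.37) and groEL (−1.69 ± 0.31), the chaperone gene dnaK (−1.28 ± 0.23) and ispG of isoprenoid synthesis (−2.05 ± 0.28) also fell. Higher in filaments were prfA for peptide chain release factor 1 (2.04 ± 0.34), hemH for ferrochelatase, the last enzyme of haem synthesis (1.89 ± 0.22), secY for the protein export channel (1.84 ± 0.20) and rnhB for ribonuclease HII (1.82 ± 0.21). The rRNA methyltransferase gene ksgA (1.54 ± 0.15) and the holo-acyl carrier protein synthase gene acpS (1.36 ± 0.17) were higher too. The normalised read count of hemH was 656 ± 38.9 CPM in spiral cells and 2428 ± 673 in filaments, and that of flgI was 2276 ± 986 and 471 ± 227. The haem gene hemH lies at 466450 to 467361 on the minus strand and flgI at 1391925 to 1392971 on the plus strand of the PT14 chromosome.

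By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 688 of 1554 genes changed (44.3%), 363 higher and 325 lower in filaments, and 145 and 114 of these by at least 2-fold. Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 2.69e-05 for ksgA, 8.57e-05 for hemH and 0.00101 for flgI. All 3 filaments lay on 1 side of all 3 spiral libraries in each, as the rule for named genes required. Among genes with a tag only, A911_03660 rose by 1.92 ± 0.27 and A911_07060 fell by 2.90 ± 0.28. The groups did not overlap in 57.7% of genes, against 10% by chance. With library totals in place of TMM, the median of all genes moved from 0.02 to 0.47 and the split was 689 higher and 104 lower, so each direction is relative to the TMM scale. A converging neighbour lay within 200 bases of prfA, hemH, secY, rnhB, acpS and flgH, the last of which converges with ispG. That of rnhB did not pass (0.06), and those of prfA, hemH, secY and acpS rose by 1.18, 1.91, 1.19 and 0.52.

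Of the lists, flagellar filament, hook and rod fell in filaments, with 9 of 11 members lower (9 adjusted over the list alone), a median of −1.40 and an adjusted p of 0.000993 by limma's camera; with library totals only, 8 members were lower and 2 higher. The adjusted p = 0.449 with an estimated correlation (2.31e-06 to 0.449 over the alternatives). The 11 members of the list held no flagellin or filament cap gene (flaA, flaB, flaC, flaD or fliD), since none of these carries a symbol. Besides the genes above, flgK for a hook-filament junction protein (−1.40 ± 0.21), the hook protein gene flgE (−1.46 ± 0.29) and fliE (−1.14 ± 0.23) fell, while flgG (−0.04 ± 0.20) and fliL (0.14 ± 0.20) did not pass. In the list of flagellar export, motor and regulators, 7 of 13 members were higher and 0 lower (7 and 0 adjusted over the list alone), led by the export gate gene fliP (1.26 ± 0.34) and the motor stator gene motB (1.03 ± 0.17). This list did not pass (adjusted p = 0.118 by camera). Filament replicate 3 lay nearest to the spiral cells in flgI, flgD and hemH.

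The citric acid cycle list had 4 of 6 members lower (4 adjusted over the list alone), namely sucC (−1.21 ± 0.13), oorD, oorA and fumC, with a median of −0.69, and did not pass (adjusted p = 0.0702 by camera); with library totals only, 1 member was lower. This list passed without exponential replicate 1 (0.0418), in a fit of only the 6 libraries compared (0.0471) and against genes with symbols alone (0.0483). DNA replication had 4 of 7 members higher (4 adjusted over the list alone), namely rnhB, dnaE, ligA and gyrB, with a median of 0.53 and an adjusted p of 0.118 by camera. Without genes that have a converging neighbour, 4 members were left, 1 of them higher, with a median of 0.24, and 3 of 9 members of flagellar export, motor and regulators were higher. Heat shock, chaperones and proteases had 3 of 7 lower, the chaperone genes above, and 1 higher, the ATPase gene clpX of the ClpXP protease (1.15 ± 0.17). Ribosomal proteins had 6 of 49 members higher and 6 lower (5 and 5 adjusted over the list alone; 18 and 1 with library totals only), with a median of −0.02. Translation factors had 4 of 10 higher, among them infC for initiation factor 3 (1.57 ± 0.19), and 1 lower (6 and 1 adjusted over the list alone). Aminoacyl-tRNA synthetases had 4 of 15 higher and 1 lower, RNA polymerase and transcription factors 2 of 7 higher, including rpoB (1.02 ± 0.14), and 1 lower, and gluconeogenesis 1 of 4 higher and 1 lower. Amino acid biosynthesis had 4 of 14 lower and 0 higher (3 and 0 adjusted over the list alone), which became 0 lower and 4 higher with library totals only. Sec, Tat and outer membrane assembly had 1 of 8 higher and 2 lower, which became 2 higher and 0 lower with library totals only. Peptidoglycan and cell shape had 2 of 9 higher (1 adjusted over the list alone), DNA repair 1 of 8 higher (0 adjusted over the list alone), fatty acid and phospholipid synthesis 2 of 5 higher (2 higher and 1 lower adjusted over the list alone) and purine and pyrimidine biosynthesis 0 of 10 changed. With library totals only, which raise the median of all genes, 9 aminoacyl-tRNA synthetase genes were higher and 0 lower. The same held for 8 genes of translation factors, 10 of flagellar export and motor, 6 of DNA replication, 4 of DNA repair, and 3 each of purines and pyrimidines, gluconeogenesis, peptidoglycan, fatty acids and RNA polymerase. Of heat shock genes, 2 were higher and 3 lower. Of the fixed genes, rpsA rose by 0.55 ± 0.19, a call that ended without any 1 of 6 libraries (0.41 to 0.57), namely exponential replicates 2 and 3, stationary spiral replicates 1 and 3 and filament replicates 1 and 2. The genes dnaA (0.35 ± 0.16), recA (−0.10 ± 0.14) and fliA (−0.46 ± 0.21) did not pass, but dnaA did with library totals only (0.79) and fliA without filament replicate 3 (−0.73).

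**Figure D3:**
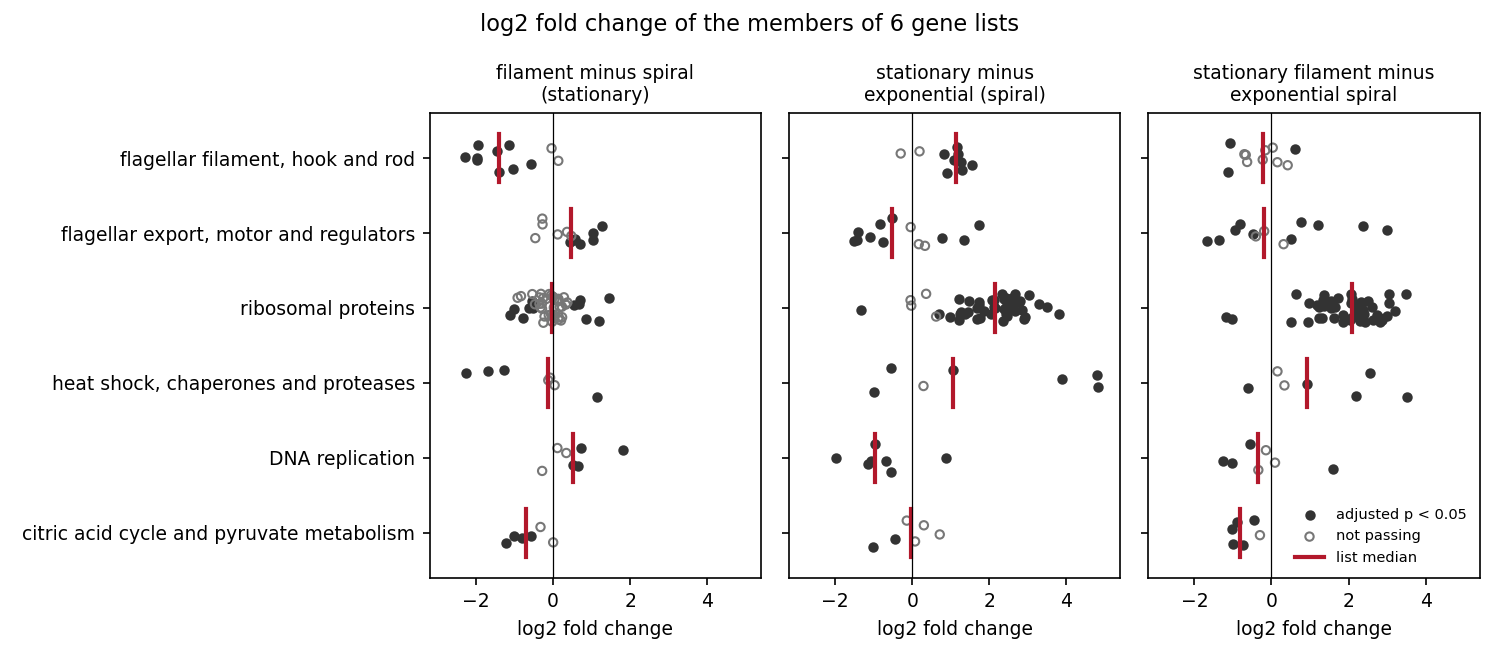
log2 fold change (x axis) of each member of 6 gene lists in the 3 comparisons, where filled points passed at an adjusted p below 0.05, open points did not, and red lines are list medians. The flagellar filament, hook and rod list had medians of −1.40, 1.14 and −0.23 from left to right on the TMM scale (−0.91, 0.38 and −0.46 with library totals only).

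The comparison of stationary with exponential spiral cells asks what changes with growth phase within the spiral form. The chaperone gene dnaK rose from 531 ± 58.0 to 14762 ± 4606 CPM (4.80 ± 0.27 log2, n = 3 and 3), groES by 4.81 ± 0.41 and groEL by 3.89 ± 0.33. Ribosomal protein genes rose by 3.82 ± 0.64 (rpsJ), 3.49 ± 0.17 (rplC), 3.30 ± 0.18 (rplW) and 3.03 ± 0.53 (rpsF), and rpmB fell by 1.33 ± 0.18. In exponential replicate 1, rpsJ had only 35 reads and rpsF 25. Without that library their rises were 3.32 and 2.56. Lower in stationary spiral cells were trpA for the alpha subunit of tryptophan synthase (−2.10 ± 0.18), rnhB (−1.97 ± 0.21), the flagellar regulator gene flhF (−1.39 ± 0.17), the D-alanine ligase gene ddl (−1.36 ± 0.23) and the primase gene dnaG (−1.14 ± 0.14).

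By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 922 of 1554 genes changed (59.3%), 435 higher and 487 lower, and 262 and 204 of these by at least 2-fold. In the same test with Benjamini-Hochberg adjustment, edgeR gave an adjusted p of 1.03e-07 for dnaK and rplC and 1.91e-06 for trpA. The 3 libraries of 1 phase all lay above those of the other in each, as the rule for named genes required. The groups did not overlap in 65.1% of genes, against 10% by chance. With library totals only, the median of all genes moved from −0.07 to −0.77 and the split was 188 higher and 916 lower. Without stationary spiral replicate 2, the largest rise, in A911_06725, moved from 6.72 to 5.99. A converging neighbour lay within 200 bases of groEL, where it rose by 4.16, and of rnhB, where it fell by 1.11.

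The list of ribosomal proteins rose, with 44 of 49 members higher and 1 lower (44 and 1 adjusted over the list alone), a median of 2.14 and an adjusted p of 7.47e-18 by limma's camera. The adjusted p = 0.0514 with an estimated correlation (1.72e-28 to 0.0514 over the alternatives). With library totals only, 41 members were higher and 3 lower, with a median of 1.45. The cluster from rplO to rpsJ, at 1606680 to 1615159 on the minus strand, held 20 adjacent genes that all rose. In the same libraries the levels of neighbouring genes in a series, ribosomal protein genes left out, correlated with a Spearman rho of 0.265 to 0.383 in exponential cells and 0.463 to 0.475 in stationary spiral cells (across genes, which are not independent replicates). Exponential replicate 1, with the lowest rho, also had the lowest median level of ribosomal protein genes, at percentile 71.7 of all genes against 78.0 and 78.5. The order was not the same elsewhere, since stationary spiral replicate 2, with the highest rho of its group, had the lowest percentile (92.0), and exponential replicates 2 and 3 ranked in opposite orders.

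**Figure D4:**
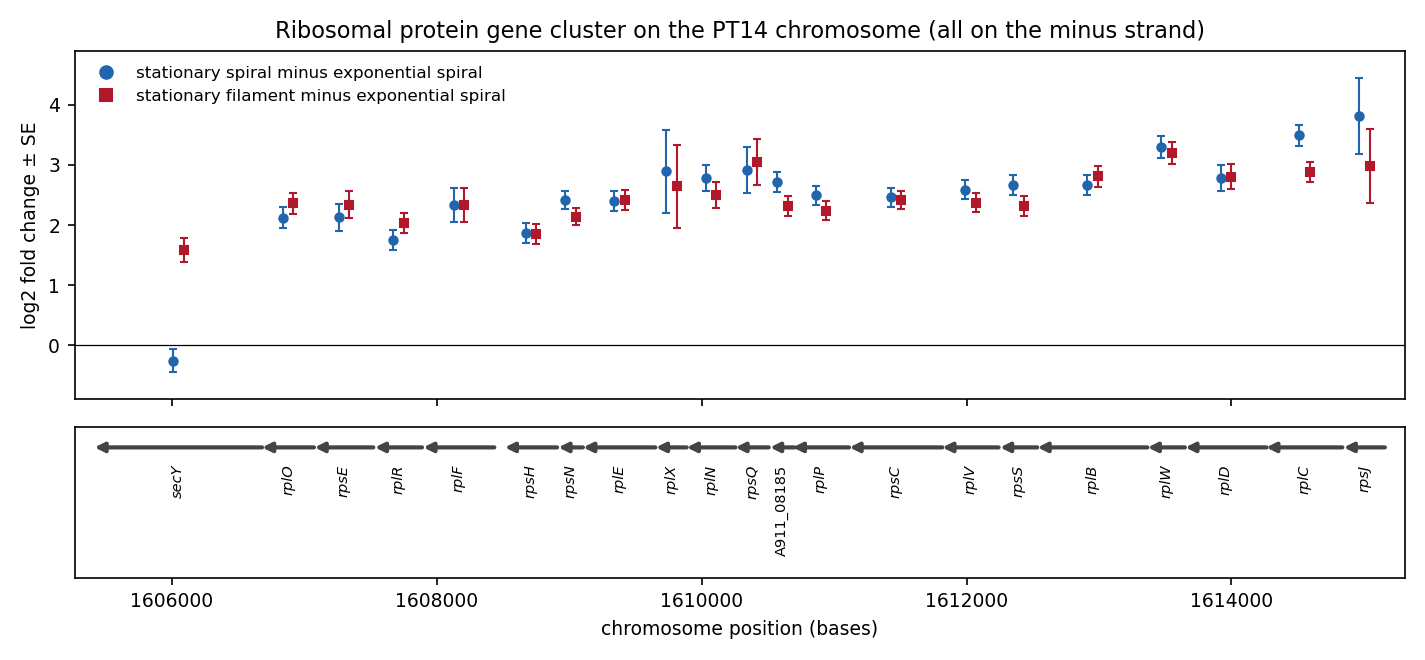
log2 fold change ± SE (y axis, n = 3 per group) of the genes from secY to rpsJ against their position on the PT14 chromosome (x axis, bases), with arrows for the genes below. The 20 genes from rplO to rpsJ rose in both comparisons with exponential cells, with medians of 2.63 and 2.39, and secY rose in filaments (1.59) and not in stationary spiral cells (−0.26).

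Flagellar filament, hook and rod genes, with no flagellin among them, also rose in stationary spiral cells. Of 11 members, 9 were higher and 0 lower (9 and 0 adjusted over the list alone). The members with the smallest p by edgeR's quasi-likelihood test were fliE (1.56 ± 0.23), fliS (1.19 ± 0.15) and flgK (1.17 ± 0.21). The call of flgK ended with library totals only (0.45), as did that of the flagellar sigma factor gene fliA, which rose by 0.77 ± 0.21 with TMM and stood at 0.05 without it. The list had a median of 1.14 and an adjusted p of 0.0391 by camera; with library totals only, 2 members were higher and 2 lower. Its adjusted p = 0.803 with an estimated correlation. The call also ended without exponential replicate 1 (0.0972), without stationary spiral replicate 2 (0.0828), without the 2 libraries that stood apart (0.0717), without genes that have a converging neighbour (0.0680) and against genes with symbols alone (0.368), over a range of 0.0181 to 0.803 by camera. The fry test, which does not compare the list with other genes, gave 0.00725. Of flagellar export, motor and regulators, 3 of 13 were higher and 7 lower (3 and 7 adjusted over the list alone), with rises in fliP (1.74 ± 0.34), motB (1.33 ± 0.17) and fliA and falls in fliG (−1.52 ± 0.16) and fliH (−1.42 ± 0.21).

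DNA replication had 6 of 7 members lower (6 adjusted over the list alone), including gyrB for DNA gyrase (−1.08 ± 0.13) and the initiator gene dnaA (−0.69 ± 0.16), and dnaE for the polymerase III alpha subunit was higher (0.87 ± 0.18); the list median was −0.97 and the adjusted p 0.0889 by camera. Against genes with symbols alone this list passed (0.0188). Heat shock, chaperones and proteases had 4 of 7 higher, the 3 chaperone genes and tig for trigger factor (1.05 ± 0.15), and 2 lower, clpX and hslU, with an adjusted p of 0.149 by camera (0.0193, and so past the threshold, with library totals only). Peptidoglycan and cell shape had 3 of 9 higher, murD (2.26 ± 0.32), mraY (1.95 ± 0.26) and alr (1.61 ± 0.20), and 3 lower, ddl, murG and murE. Amino acid biosynthesis had 6 of 14 higher and 5 lower, the falls led by trpA and aroE (−1.97 ± 0.19). Sec, Tat and outer membrane assembly had 4 of 8 higher, led by secG (1.71 ± 0.16), and 2 lower. Translation factors had 4 of 10 higher and 3 lower, RNA polymerase and transcription factors 2 of 7 and 1, purine and pyrimidine biosynthesis 4 of 10 and 2, and fatty acid and phospholipid synthesis 2 of 5 and 1. DNA repair had 2 of 8 higher and 3 lower, aminoacyl-tRNA synthetases 2 of 15 and 3, the citric acid cycle 0 of 6 and 2 (0 and 1 adjusted over the list alone), and gluconeogenesis 0 of 4 and 1. With library totals only, the lists of amino acid biosynthesis (0 higher and 7 lower), Sec and outer membrane assembly (2 and 4), translation factors (2 and 6), RNA polymerase (0 and 4), purines and pyrimidines (0 and 4) and fatty acids (1 and 2) turned to more members lower than higher. The same scaling gave 0 higher and 12 lower in aminoacyl-tRNA synthetases, 3 and 6 in peptidoglycan and cell shape, 0 and 5 in DNA repair, 0 and 5 in the citric acid cycle and 0 and 4 in gluconeogenesis. It gave 0 and 6 in DNA replication, 2 and 8 in flagellar export and motor and 3 and 3 in heat shock. The fixed genes rpsA (−0.04 ± 0.19) and recA (−0.23 ± 0.14) did not pass, but did with library totals only (−0.77 and −0.93).

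The comparison of stationary filaments with exponential spiral cells asks how far filaments depart from growing cells. The gene dnaK rose by 3.52 ± 0.25 log2 (n = 3 and 3), to 6093 ± 312 CPM, and ribosomal protein genes by 3.48 ± 0.23 (rplM), 3.20 ± 0.18 (rplW), 3.06 ± 0.21 (rpsI), 3.05 ± 0.38 (rpsQ), 2.88 ± 0.17 (rplC) and 2.81 ± 0.17 (rplB). Release factor gene prfA (3.07 ± 0.35) and fliP (3.00 ± 0.36) rose as well. Lower in filaments were trpA (−2.49 ± 0.18), flhF (−1.66 ± 0.17), the lipoprotein carrier gene lolA (−1.55 ± 0.18), gidB (−1.48 ± 0.39), the glycyl-tRNA synthetase gene glyQ (−1.46 ± 0.16) and rpmB (−1.18 ± 0.18).

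By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 860 of 1554 genes changed (55.3%), 437 higher and 423 lower, and 225 and 167 of these by at least 2-fold. The adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 4.67e-07 for dnaK and 5.02e-07 for trpA. All 3 filaments lay on 1 side of the exponential libraries in both, as the rule for named genes required. The groups did not overlap in 62.9% of genes, against 10% by chance. Tag-only gene A911_06725 rose by 7.57 ± 0.74 and A911_00055 fell by 3.11 ± 0.30. With library totals only, the median of all genes moved from −0.01 to −0.25 and 35.2% of the changed genes were higher, against 50.8% with TMM. A converging neighbour lay within 200 bases of prfA, where it rose by 3.29, of fliP, where it fell by 0.80, of lolA, where it fell by 0.88, and of gidB, where it did not pass (−0.78).

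Ribosomal proteins rose, with 47 of 49 members higher and 2 lower, rpmB and rplI (−1.02 ± 0.21), in the test over all genes and adjusted over the list alone. The list median was 2.08, with an adjusted p of 4.58e-18 by limma's camera and, as the only list call of the 3 comparisons that held, an adjusted p = 0.0499 with an estimated correlation (2.95e-22 to 0.0499 over the alternatives). The Spearman rho of neighbouring levels in a series, ribosomal protein genes left out, was 0.479 to 0.518 in filaments. Heat shock, chaperones and proteases had 4 of 7 members higher, dnaK, groES (2.56 ± 0.38), groEL (2.20 ± 0.31) and tig, and 1 lower, hslU (5 and 1 adjusted over the list alone; adjusted p = 0.120 by camera). The citric acid cycle had 5 of 6 lower (5 adjusted over the list alone), including oorC (−1.01 ± 0.14), fumC for fumarase (−1.01 ± 0.18) and sucC for a succinyl-CoA synthetase subunit (−0.90 ± 0.13), and did not pass (adjusted p = 0.0671 by camera). It passed without exponential replicate 1 (0.0137), without the 2 libraries that stood apart (0.0180) and against genes with symbols alone (0.00790). Translation factors had 6 of 10 higher, led by infA for initiation factor 1 (3.08 ± 0.50), prfA and tsf for elongation factor Ts (2.00 ± 0.16), and 2 lower (adjusted p = 0.178 by camera). Flagellar filament, hook and rod had 1 of 11 higher and 2 lower, flgI (−1.12 ± 0.36) and flgD (−1.08 ± 0.34), and flagellar export, motor and regulators 5 of 13 higher, including motB (2.37 ± 0.18), and 5 lower. The count of flagellar filament, hook and rod genes was 0 higher and 5 lower with library totals only, 1 and 7 without the 2 libraries that stood apart, 1 and 6 without filament replicate 3, and 1 and 0 without filament replicate 1 or 2. Sec, Tat and outer membrane assembly had 6 of 8 higher and 2 lower, RNA polymerase and transcription factors 4 of 7 and 1, fatty acid and phospholipid synthesis 2 of 5 and 0, and purine and pyrimidine biosynthesis 2 of 10 and 1 (2 and 0 adjusted over the list alone). Peptidoglycan and cell shape had 3 of 9 higher and 3 lower, DNA replication 1 of 7 and 3, DNA repair 1 of 8 and 1, gluconeogenesis 0 of 4 and 2, and amino acid biosynthesis 3 of 14 and 6. Aminoacyl-tRNA synthetases had 5 of 15 higher and 3 lower, which became 2 higher and 3 lower with library totals only. That scaling also gave 45 and 2 in ribosomal proteins, 4 and 6 in flagellar export and motor, 0 and 3 in DNA repair and 1 and 4 in DNA replication. The counts were 5 and 2 in translation factors, 3 and 1 in RNA polymerase, 4 and 2 in Sec and outer membrane assembly and 1 and 1 in purines and pyrimidines. The gene rpsA rose by 0.51 ± 0.19, a call that ended without any 1 of 5 libraries (0.41 to 0.51), exponential replicates 2 and 3, stationary spiral replicate 3 and filament replicates 1 and 2, and with library totals only (0.26). The genes fliA (0.31 ± 0.21), recA (−0.33 ± 0.14) and dnaA (−0.34 ± 0.15) did not pass. The genes recA (−0.58) and dnaA (−0.58) passed with library totals only, and so did recA without exponential replicate 1 (−0.36).

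**Figure D5:**
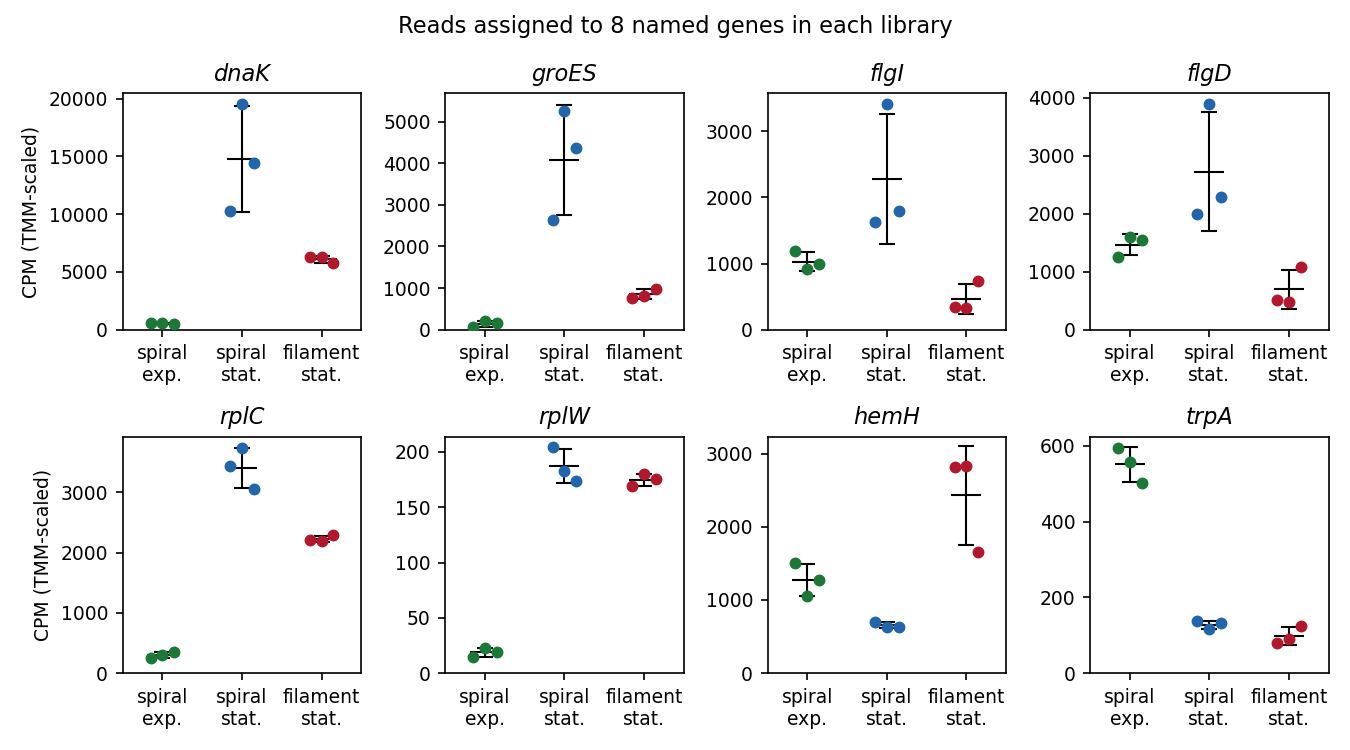
Normalised read counts (CPM, y axis) of 8 named genes in the 3 groups (x axis), with a point per library, a line at the mean and bars of 1 SD (n = 3). The flagellar gene flgI averaged 1029 in exponential spiral cells, 2276 in stationary spiral cells and 471 in filaments, and dnaK 531, 14762 and 6093.

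Of the genes changed in both comparisons with exponential cells, 278 were higher in both and 280 lower in both, among them dnaK, rplC and trpA, and 36 changed in opposite directions, among them hemH. That count ranged from 17 without exponential replicate 3 to 79 without the 2 libraries that stood apart, and only 9 of the 36 remained among 46 such genes with library totals only. The opposite calls of flgI and flgD were lost with that scaling (0.38 and 0.14 in stationary spiral cells) and in 6 of the 9 fits without 1 library each. Independent lists of these sizes would share 122 higher and 133 lower genes. Pearson's r of the log2 fold changes was 0.747 across genes. Its mean was 0.462 in 20 simulations of unchanged groups with shared controls, in which at most 1 gene was shared. All libraries there, the exponential ones included, were redrawn gene by gene around the exponential means. Deviations common to many genes, such as those of exponential replicate 1, were therefore left out. The covariance was 0.849, against 0.0302 simulated. The 3 exponential libraries cannot be split into sets of 2 or more, so part of the excess may come from sharing them. A further 328 genes changed only in stationary spiral cells and 266 only in filaments, of which 242 and 189 also differed between the morphotypes by the direct comparison.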

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

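Chosen only after the result was seen were the correlation and level tests of converging neighbours, the test of own-strand reads in exponential libraries, and the bootstrap intervals and length-matched random lists for ribosomal protein genes. The bounds of the other tests were also written after the changed genes and lists had been seen, but before the values of those tests were computed.

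In the comparisons with exponential cells, 36 genes changed in opposite directions in stationary spiral cells and in filaments on the TMM scale, a count that ranged from 17 to 79 over the alternatives, and 9 of the 36 kept both calls with library totals only. The difference between these 2 changes is the filament against spiral contrast of the same fit, so that such genes pass it by edgeR follows almost from their selection and is no separate evidence. Of these, 14 were higher in stationary spiral cells and lower in filaments, and 22 went the other way. Among the 8 with symbols, flgI differed between filaments and stationary spiral cells by −2.27 (1.14 ± 0.35 in spiral cells and −1.12 ± 0.36 in filaments, each against exponential cells), ispG by −2.05 and flgD by −1.97. The difference was 1.89 in hemH (−0.96 ± 0.21 and 0.93 ± 0.21), 1.74 in atpC for a subunit of ATP synthase (−1.13 ± 0.15 and 0.61 ± 0.14), 1.54 in ksgA, 1.02 in rpoB and 1.02 in pcm for a protein repair methyltransferase. Of the 8, hemH and ksgA alone kept both calls with library totals only, and flgI and flgD also lost 1 of theirs, or both, without any 1 of 6 libraries. The genes hemH, ispG and pcm have a converging neighbour, so their values are uncertain. That of hemH rose by 1.91 in filaments against spiral cells. With such genes left out, flgD lost its call in stationary spiral cells (0.87). Without exponential replicate 3, ksgA lost its call in stationary spiral cells and rpoB its call in filaments. The latter was also lost without filament replicate 1.

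Ribosomal RNA features, which the comparisons leave out, held a mean of 1.89% of gene reads in stationary spiral cells and 3.27% in filaments, where filament replicate 2 had 6.90%, against 0.671% in exponential cells. Reads with several matches, the difference between the 2 read columns, made up a mean of 6.82% in stationary spiral cells and 5.44% in filaments, against 3.10% in exponential cells.

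The number of changed genes was set against other splits of the 6 libraries of each comparison, fitted on their own. The real split gave 741 genes for filaments against spiral cells, 866 for stationary against exponential spiral cells and 820 for filaments against exponential cells, and the highest of the other splits gave 0 in each by edgeR. Only 1 split of 10, the real one, gave as many in each comparison, and 10 splits are too few for a share under 0.05.

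Ribosomal protein genes were higher in stationary spiral cells, with a median log2 fold change of 2.14 (quartile 1 of 1.44, 49 members), a list call that ended with an estimated correlation (adjusted p = 0.0514 by camera). Gene length as the whole account is argued against by a median of 1.71 (95% interval 1.31 to 2.11) with the length trend of all genes removed. In addition, 0 of 10000 length-matched random lists were as high (highest 0.924). Those lists drew genes singly, whereas many ribosomal protein genes adjoin in series that can share a transcript, so the spread of the lists is too narrow. The intervals over genes share this limit. Scaling by TMM as the whole account is argued against by a median of 1.45 (1.01 to 1.72) with library totals only. Quartile 1, which had been required to stay above 1 when these tests were set, was 0.90 and 0.77 in these 2 tests and missed that bound. In the 46 of 49 members without a converging gene within 200 bases, the median was 2.13 and quartile 1 was 1.38. For these members this argues against reads from such a neighbour. Opposite-strand reads from other sources were not tested by this. A smaller share of own-strand reads in exponential libraries may lower abundant genes there. The lowest stationary correlation of neighbouring levels lay 0.0801 above the highest exponential one. Within groups, libraries did not rank alike in that correlation and in ribosomal protein level. With 3 libraries per group, that ranking cannot decide for or against this source. Because the exponential libraries form 1 group, this source cannot be told apart from a change with growth phase, which stays open as untested.

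Log2 fold changes of converging neighbours correlated (Spearman rho across 154 pairs of 0.545 for filaments against spiral cells, 0.516 for stationary against exponential spiral cells and 0.568 for filaments against exponential cells), and the smallest difference from diverging neighbours was 0.466 (95% interval 0.254 to 0.675). A shared chromosomal neighbourhood was argued against by the 132 diverging pairs, whose largest rho was 0.0507 (−0.117 to 0.225). A candidate explanation is that reads from the opposite strand were counted, since the level step into genes that end at a converging gene exceeded that into other genes by 1.59 or more in every library. Under this explanation a called value such as that of hemH, secY or prfA could belong in part to its neighbour, and groEL and its neighbour rose by 3.89 and 4.16 in stationary spiral cells, but not all pairs moved together: rnhB rose by 1.82 in filaments against spiral cells where its neighbour gltD stood at 0.06, and fliP rose by 3.00 in filaments against exponential cells where its neighbour fell by 0.80. Transcription that truly runs past the ends of both genes was not tested and stays open.

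Filament replicate 3 lay at −9.25 on component 2, between the other filaments (−17.4 and −18.2) and the stationary spiral cells (13.8 to 15.3). On the way from spiral cells (0) to filament replicates 1 and 2 (1), its median position was 0.811 in 309 genes higher in those filaments and 0.617 in 66 genes lower in them. The difference of 0.194 (95% interval 0.126 to 0.279) argues against a mixture with the mean RNA of stationary spiral libraries, which predicts equal positions. The interval reaches below the difference that had been required, and it leaves out the spread between libraries. Those libraries differed, with flgI at 1630, 3412 and 1787 CPM in replicates 1, 2 and 3. A mixture with RNA unlike their mean was not tested and stays open. A shift towards exponential-phase RNA also stays open, since the median position between exponential cells and the other filaments was 0.897 (0.864 to 0.925) in 205 genes and its interval spans the bound set for that test. A biological difference between cultures, such as shorter filaments, was not tested.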

How the results depend on the processing

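Chosen only after the data were seen were the alternatives with unique reads, without the 2 libraries that stood apart, without genes that have a converging neighbour, and with a background of genes with symbols. Named genes, each in the comparisons where the rule chose it, were followed over part of the alternatives. These were DESeq2 size factors, library totals only, the DESeq2 Wald test, the replicate block, unique reads and the fits without 1 library. There, 951 values kept their direction and side of the threshold, 16 lost their call, 7 gained one and 6 reversed. None of the reversed values had been called. They were recA (0.35) and fliA (0.0245) between morphotypes with library totals only, and rpsA between phases of spiral cells with DESeq2 size factors (0.00418), with the DESeq2 Wald test (0.00411) and in 2 of the fits without 1 library (range −0.174 to 0.0932). Among these values the lost calls were those of rpsA, flgK and fliA. Genes outside the rule, such as flgI and flgD between phases, are not in this tally. Calls were gained with library totals only by dnaA between morphotypes (0.79), by rpsA (−0.77) and recA (−0.93) between phases, and by recA and dnaA in filaments against exponential cells (−0.58 each). Without filament replicate 3, fliA gained a call between morphotypes (−0.73), and without exponential replicate 1, recA in filaments against exponential cells (−0.36). The cause was not tested.

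Library totals in place of TMM gave 689 higher and 104 lower genes in filaments against spiral cells and 188 higher and 916 lower in stationary against exponential spiral cells, because the median of all genes moved with the scaling. Of the 688 and 922 genes called with TMM, 467 and 675 were called again, and 24 and 91 changed sign, whether called again or not. All other counts of genes changed, higher or lower in a comparison stayed within 1.5 times those reported. The count of genes changed in opposite directions did not, at 17 to 79 against 36. Counts of changes of at least 2-fold were not repeated. The count of filaments against spiral cells ranged from 508 without filament replicate 2 to 803 without exponential replicate 1, that of stationary against exponential spiral cells from 804 to 951, and that of filaments against exponential cells from 729 to 892. Unique reads gave 688, 925 and 860 genes, leaving out the 2 libraries gave 861, 1022 and 942, and leaving out genes with a converging neighbour, with 1236 genes tested, gave 529, 720 and 665.

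The number of lists that passed was 1, 2 and 1 in the 3 comparisons in that order. With an estimated correlation it was 0, 0 and 1 by camera, where the p of each list grows with the correlation between its members. By fry, which does not compare a list with other genes, it was 9, 10 and 10. A background of genes with symbols gave 2 in filaments against spiral cells and 2 in filaments against exponential cells, adding the citric acid cycle (adjusted p = 0.0483 and 0.00790). In stationary against exponential spiral cells it also gave 2, where flagellar filament, hook and rod dropped out (0.368) and DNA replication passed (0.0188). A fit of only the 6 libraries gave 2 in filaments against spiral cells, adding the citric acid cycle (0.0471). Without the 2 libraries that stood apart, 1 list passed in stationary against exponential spiral cells and 2 in filaments against exponential cells, and without converging genes 1 list passed in the former. Leaving out 1 library gave between 1 and 2 lists in each comparison. The causes of these differences were not tested, except that fry asks another question.

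The counts showed no pairing of libraries by replicate number. Deviations of libraries with the same number correlated between −0.0865 and 0.0959, and not every library correlated best with its own number. With 3 libraries per group this cannot settle whether spiral and filament fractions came from the same cultures. With the replicate block, 654, 897 and 842 genes changed, and rpsA lost its call in filaments against spiral cells (0.54) and against exponential cells (0.50). Leaving out a library left 2 in its group. At this depth, with 3 libraries per group, simulated data recovered 22.4% to 40.3% of 1.5-fold changes. Far fewer genes changed there than were called in the real data, and depth was not varied. Alternatives for pseudocounts and filters of normalised values were not run because the files hold counts.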

Other observations

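Chosen only after the data were seen were the grouping of adjacent genes and the genes named here from lists too small to test.

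Several series of at least 6 adjacent genes on 1 strand changed together. Between filaments and spiral cells, 4 such series were higher and 1 was lower. A series of 7 genes with atpC at 111954 to 117902 on the plus strand was higher in filaments, with a median of 1.74, and another of 6 at 199044 to 208019 held thrS for threonyl-tRNA synthetase (1.03 ± 0.17) and infC (1.57 ± 0.19). In 2 further series, of 6 genes between tolB and lpxC and of 6 between acpS and prfB, the medians were 1.81 and 1.60 in filaments against spiral cells and −1.76 and −1.83 in stationary against exponential spiral cells, but 0.13 and 0.14 in filaments against exponential cells. The lower series, 6 genes between frdB and murD, had a median of −1.21 in filaments.

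With growth phase in spiral cells, 4 series rose and 7 fell. A series of 6 genes around dnaK at 707085 to 714382 on the plus strand rose by a median of 3.31 in stationary spiral cells and 1.98 in filaments. The series with secE, nusG, rplK, rplA, rplJ and rplL at 435691 to 438649 rose by a median of 1.24, and the flagellar genes fliF, fliG and fliH lay in a series of 6 that fell by a median of 1.09. In filaments against exponential cells, 10 series rose, including a series of 18 genes at 104584 to 117902 with rplU, rpmA, obgE, fmt and atpC (median 1.23), and 1 fell. Neighbours in a series can share a transcript, and their counts are not independent.

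From lists with fewer than 4 members, frdB for a subunit of fumarate reductase rose by 1.46 ± 0.38 in stationary spiral cells and by 1.26 ± 0.38 in filaments against exponential cells. The gene lpxC, for a deacetylase of lipid A synthesis, fell by 0.57 ± 0.15 and 0.67 ± 0.14. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of frdB was 0.00829 and 0.0177 and that of lpxC 0.00497 and 0.00180.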
